A study of Mus musculus with 12 samples.

How the data were processed

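RNA of micro-dissected palatal shelves was sequenced from 12 single mouse embryos of the C57BL/6 strain, labelled embryonic day 14. The embryos were Pax9 homozygous mutants or control littermates, from dams left untreated or given WAY-262611, a small-molecule Wnt agonist, by daily tail-vein injection from embryonic day 10.5 to day 14. RNA was extracted with a column kit and made into oligo(dT)-selected TruSeq libraries. The deposited table holds FPKM values (fragments per kilobase of gene, scaled to library size) for 19083 genes in 12 columns, made by the authors. Novoalign 2.08.03, DESeq2 and the genome build mm10 are named in the submitters' processing notes. The gene annotation, the counting tool, the strand setting and the rule that left 19083 genes are not given in the sources used here.

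Because FPKM values are not counts, no count model was fitted to the deposited values. Each gene's values were tested for being whole multiples of 1 read, and this held within 0.001 read for 19080 of 19083 genes (99.98%). The recovered totals were 36.8 to 49.8 M reads per library, and they serve as the depth. No pair of libraries within a group was a copy of another, since the chi-square per degree of freedom between replicates ran from 4.35 to 103.37. A gene symbol, position, GC content and transcript length were looked up by gene identifier in the GENCODE mouse annotation, release M21, for 18752 genes.

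The 4 groups were untreated control, untreated mutant, WAY-treated control and WAY-treated mutant, with 3 embryos each. Controls were wild-type and heterozygous embryos pooled. The number shared by sample titles (389, 393, 318 and 422) was read as the litter, which the labels do not say in words. Litters 389 and 393 were untreated, and 318 and 422 were treated. The prefixes of the column names split the libraries into a batch of 4 (litters 389 and 318, 1 library per group) and a batch of 8 (litters 393 and 422, 2 libraries per group). Within a batch, treatment and litter cannot be told apart.

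The groups, gene lists, rule for named genes, tests and alternative settings were fixed before the data were examined. Genes with at least 1 FPKM in at least 3 samples were kept (14107 of 19083). Values were put on the log2(FPKM + 0.5) scale, and fold changes on it understate the change of genes near the floor. Each comparison was tested with limma 3.58.1 in R 4.3.3 (group means over all 12 samples, moderated with a trend), and p values were adjusted by the Benjamini-Hochberg method at 0.05. The comparisons were mutant against control in untreated embryos, in treated embryos and over both treatments, WAY against untreated in mutants, in controls and over both genotypes, and the interaction. Errors of fold changes are standard errors (SE) of that fit, and p values are two-sided. In the genotype comparisons the litter was also fitted as a block, and its counts stand beside the result, with its adjusted p for selected genes. Where treatment was tested, litter was fitted as a random effect with a consensus correlation of 0.5. After the column names and principal components had been seen, the batch was added as a term and the 8-library batch was fitted alone. The 4-library batch holds 1 library per group and gives fold changes with no test.

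Lists of pathway genes, cell type markers and stress genes (27 with at least 5 genes kept) were tested with camera at a preset correlation of 0.01, adjusted over lists. Camera was repeated with an estimated correlation, and fry, which asks whether the genes of a list move on balance in 1 direction, was run beside it. Member counts are given over all genes and adjusted over the list alone. The named genes of a comparison were the 10 with the largest rise and the 10 with the largest fall that passed, had an established symbol and had no overlap between the sides. Over both treatments or genotypes the same direction in each arm was required in place of no overlap. Where fewer than 5 passed in a direction, the 5 with the smallest p were added as values. Developmental genes fixed in advance (among them Pax9, Dkk1, Axin2 and Msx1) and list members past the threshold were always included. A few genes that meet this rule are not reported here.

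Tested on simulated data with 100 changed genes per fold among 13958 genes, the fit without block recovered 61% of genes changed 1.5-fold and 88% of genes changed 2-fold in untreated mutants. Over both treatments it recovered 76% and 93%, and with the block 91% and 98%. In the treatment comparisons and the interaction, where no gene was changed, it called 0 genes. The simulated means differed by batch and held no litter effect, so these 0 calls do not cover differences between litters. No treatment or interaction effect was simulated, so the power of those comparisons is not known.

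The alternative settings chosen in advance were pseudocounts of 0.1 and 1, no filter or a filter at 5 FPKM, median-ratio scaling, a term for heterozygous embryos, a term for a score of Y-linked transcripts, each comparison fitted on its own 6 samples, the litter block, means per litter and genotype, and leaving out each library. Alternatives added after seeing the data were the batch term, batch with Y-linked score, the 8-library batch alone, voom on the recovered reads, and a spline correction for GC content and transcript length (4 degrees of freedom each) with the block or the batch term. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The extract protocol also names an earlier stage, whose data are not analysed here.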

Results

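Messenger RNA was measured in palatal shelves of 12 mouse embryos at the labelled stage of embryonic day 14. The design crosses the Pax9 genotype (homozygous mutant or control littermate) with maternal treatment (none or the Wnt agonist WAY-262611), with 3 embryos in each of the 4 groups. The untreated controls were 1 wild-type and 2 heterozygous embryos, and the treated controls were 2 wild-type and 1 heterozygous embryo. Depth ran from 36.8 to 49.8 M recovered reads per library. The series title and design pose the question of how loss of Pax9 and treatment with a Wnt agonist alter the forming palate. The first principal component (52.5% of variance) separated the 8-library batch from the 4-library batch and not the genotypes or treatments, so values within batches stand beside the pooled ones.

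**Figure D1:**
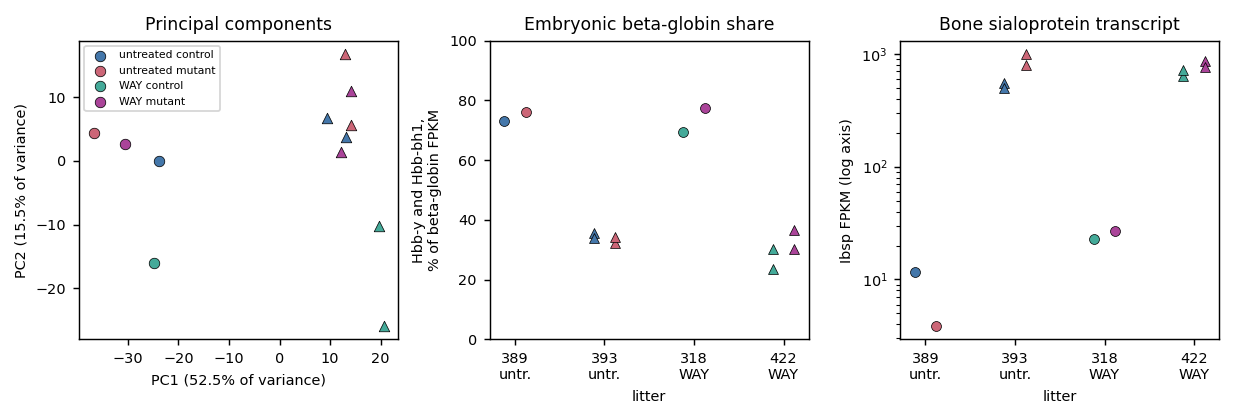
Principal components of the 12 libraries (52.5% and 15.5% of variance), the embryonic share of beta-globin FPKM and Ibsp FPKM on a log axis, by batch. The embryonic share was 69.3% to 77.4% in the 4-library batch and 23.7% to 36.5% in the 8-library batch.

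Pax9 encodes a paired-domain transcription factor needed for palate and tooth formation (chromosome 12, 56691767 to 56712822, mm10). Its transcript followed the labelled genotypes. Mutants had 5.9 ± 0.85 FPKM (SD, n = 6), heterozygous embryos 21.4 ± 1.3 (SD, n = 3) and wild-type embryos 32 ± 4.8 (SD, n = 3). Mutants thus kept 18.4% and heterozygous embryos 66.9% of the wild-type level. Where in the gene the reads of mutants lie is not known from these values. The exact permutation test of heterozygous against wild-type embryos gave p = 0.1 (two-sided), the smallest that 3 against 3 allow. All 3 heterozygous embryos are in the 8-library batch and 2 of the 3 wild-type embryos in the other, so batch and genotype are partly mixed here. The wild-type embryo of the 8-library batch had 30 FPKM. Between mutants and controls Pax9 fell by 2.04 ± 0.22 on the log2 scale in untreated embryos (SE, n = 3 per group, adjusted p = 0.016 in limma) and changed by -2.09 ± 0.22 in treated ones (adjusted p = 0.0047).

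**Figure D2:**
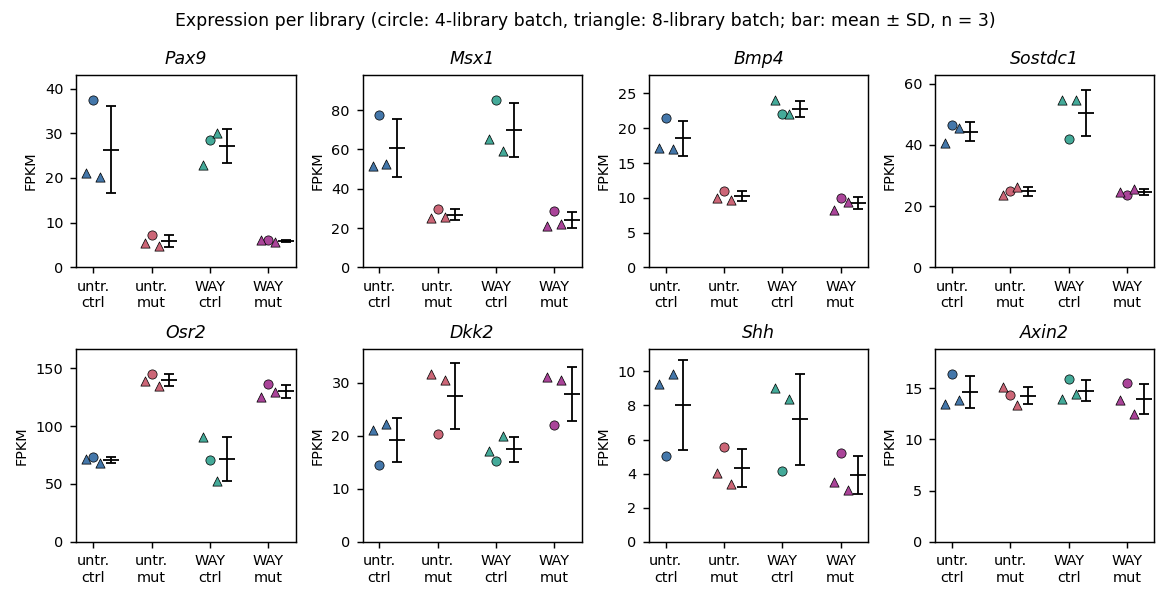
FPKM of 8 genes in each library, by group, with circles for the 4-library batch, triangles for the 8-library batch and bars for the mean ± SD (n = 3). Pax9, Msx1, Bmp4 and Sostdc1 were lower and Osr2 higher in mutants of both arms, while Axin2 stayed between group means of 13.9 and 14.8 FPKM.

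The first comparison asks what loss of Pax9 changed without treatment. The secreted growth factor Bmp4 (chromosome 14, 46383520 to 46390669) fell from 18.5 ± 2.5 to 10.2 ± 0.71 FPKM (SD, n = 3), or by 0.83 ± 0.1 on the log2 scale (SE, adjusted p = 0.021). Sostdc1, a secreted antagonist of BMP and Wnt ligands, fell by 0.82 ± 0.1 (adjusted p = 0.021). The AP-2 family transcription factor Tfap2b fell by 1.56 ± 0.22 (adjusted p = 0.03), and Hs3st6, a heparan sulfate sulfotransferase, by 1.56 ± 0.2 (adjusted p = 0.025). The cerebellin-family gene Cbln4 rose by 0.98 ± 0.14 (adjusted p = 0.03) and Brinp3 by 0.79 ± 0.1 (adjusted p = 0.029). The other falls were in Adcy8 (-1.2), Slc5a7 (-1.09), Prr15 (-0.85), Lrrtm1 (-0.68) and Id4 (-0.55), an inhibitor of helix-loop-helix factors. Msx1, a homeobox gene that acts with Pax9 in the dental and palatal mesenchyme, had a log2 fold change of -1.14 ± 0.18 that missed the threshold (adjusted p = 0.073, with the litter block 0.00015). The zinc-finger gene Osr2, needed for growth of the palatal shelf, missed it with 0.98 ± 0.15 (adjusted p = 0.051, with the block 0.031). Among genes given as values for their small p, Trpm5 had 0.47 (adjusted p = 0.073, with the block 0.011) and Tenm1 0.68 (adjusted p = 0.077, with the block 0.03).

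In total 13 genes passed in untreated embryos, 2 higher and 11 lower in mutants, and 531 had an unadjusted p under 0.05. With the litter as a block 74 passed (32 higher, 42 lower). With a term for heterozygous embryos 5 passed, 4 of them among the 13, and the 6 samples alone gave 1, which was not among the 13. The heterozygous embryos are all in the 8-library batch and that fit has no batch term. In every comparison it thus mixes heterozygosity with batch. The 8-library batch alone gave 50, where 10 of the 12 named genes passed, and all 12 had the same sign in both batches. That shared sign follows from the rule that the sides do not overlap. The 8 libraries are also part of the 12 libraries that made the calls, so this is no independent test. The count of 13 depends on single libraries. It was 0 to 6 without any of the 6 untreated libraries or without WAY mutant 2 or 3. With the block it was 17 to 46 without any untreated library or WAY mutant 2, and 149 without WAY control 2.

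Of the Wnt genes fixed in advance, Sostdc1 passed in untreated mutants without the block, and Dkk1, Dkk2, Lef1, Axin2 and Wnt5a did not. Dkk1, the secreted antagonist that WAY-262611 is known to oppose, had a log2 fold change of 0.11 ± 0.88 (adjusted p = 1), with 12.1 ± 2 FPKM in the 8-library batch and 2.43 ± 0.48 in the other. Dkk2 had 0.5 ± 0.21 (adjusted p = 1, with the block 0.013). Lef1, a Wnt-responsive transcription factor, had -0.6 ± 0.21 (adjusted p = 1, with the block 0.025). Axin2, a feedback target of canonical Wnt signalling, had -0.03 ± 0.1 (adjusted p = 1, with the block 0.97). Wnt5a had -0.32 ± 0.06 (adjusted p = 0.17), Shh -0.79 ± 0.33, Fgf10 -0.3 ± 0.16 and Tbx22 -0.03 ± 0.16 (adjusted p = 1 for each).

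Gene lists described the untreated mutants more broadly, and 10 of 27 passed camera. Dental epithelium and mesenchyme markers were lower (median log2 fold change -0.49, adjusted p = 2.9e-07). This was the only list called here with an estimated correlation (adjusted p = 0.01), and with the block it lost that call (adjusted p = 0.12 with an estimated correlation). Fry called it too (adjusted p = 0.0028), and with the batch term it called the dental and cell cycle lists (0.0023 each). Of its 13 genes, 1 fell over all genes tested and 5 fell when adjusted over the list alone. Cell cycle genes were lower, with 1 of 32 above 0 (median -0.15, adjusted p = 9.6e-12), but adjusted p = 0.35 with an estimated correlation. Oral epithelium markers were lower, with 2 of 26 above 0 (median -0.28, adjusted p = 0.0012, and adjusted p = 0.77 with an estimated correlation). Nasal and sensory epithelium markers were lower (adjusted p = 0.026, and adjusted p = 0.37 with an estimated correlation). No member of these 3 lists passed over all genes. Higher as lists were skeletal muscle (adjusted p = 1.2e-09), hypoxia and glycolysis (0.013), osteogenesis (0.016), Schwann and melanocyte (0.016) and cartilage genes (0.026), each with adjusted p = 0.77 with an estimated correlation. Pericyte and smooth muscle markers were higher (adjusted p = 0.049, and adjusted p = 0.35 with an estimated correlation). The muscle list was carried by the untreated litter of the 4-library batch, where the mutant and control differed by 1.66, while the other untreated litter had 0. Schwann and melanocyte markers (0.62 and 0) and pericyte markers (0.29 and 0) were likewise carried by that litter. The 2 untreated litters went opposite ways for osteogenesis (-0.28 and 0.36), cartilage (-0.34 and 0.43) and nasal markers (-0.48 and 0.05).

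**Figure D3:**
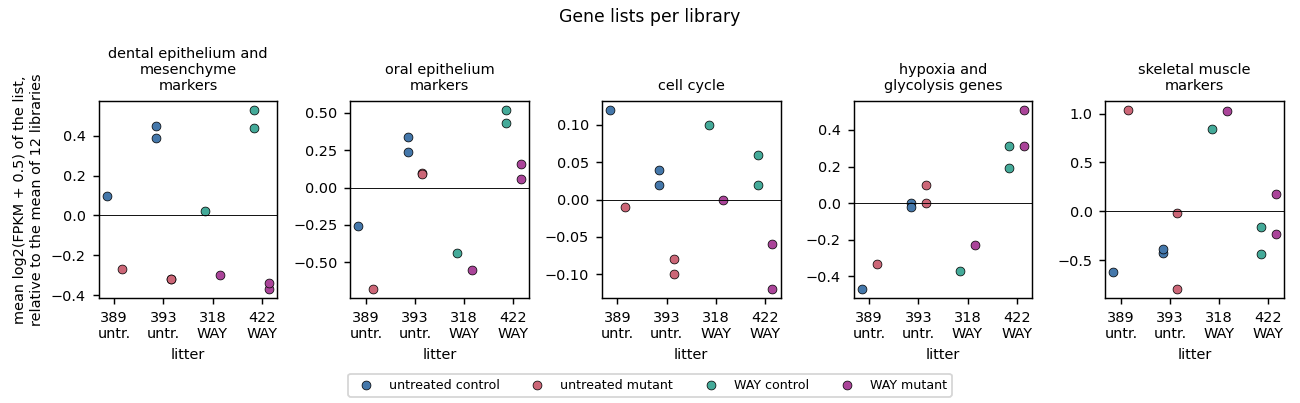
Mean log2(FPKM + 0.5) of 5 gene lists in each library, relative to the mean of the 12 libraries, with litters on the x axis and colour for the group. Dental, oral epithelium and cell cycle means were below those of littermate controls in the mutants of 4 of 4 litters, and hypoxia and glycolysis means were above them in 4 of 4.

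The second comparison asks the same of embryos treated with WAY-262611. Bmp4 fell from 22.8 ± 1.2 to 9.21 ± 0.87 FPKM (SD, n = 3), or by 1.26 ± 0.1 on the log2 scale (SE, adjusted p = 0.0008). Msx1 (chromosome 5, 37820485 to 37824583) fell by 1.52 ± 0.18 (adjusted p = 0.011) and Sostdc1 by 1.01 ± 0.1 (adjusted p = 0.0043). Osr2 (chromosome 15, 35296098 to 35303305) rose by 0.89 ± 0.15 (adjusted p = 0.037), and Gdf7, a BMP-family ligand, by 1.52 ± 0.24 (adjusted p = 0.036). Hs3st6 (-1.55), Tfap2b (-1.5), Adcy8 (-1.22), Pla2g7 (-1.12), Prr15 (-0.93), Dclk3 (-0.91), Id4 (-0.48) and the secreted Wnt modulator Sfrp2 (-0.46) also fell. Cbln4 (1.25), Tenm1 (1.11), Trpc5 (1.04), Brinp3 (0.83), Nexmif (0.8) and Slitrk4 (0.75) rose. Values at the small RNA genes Mir5117 (2.07) and Snora23 (1.56) rose too. Both were low in treated controls (3.07 ± 1.3 and 0.269 ± 0.14 FPKM, SD, n = 3). In untreated embryos neither mean was higher in mutants than in controls. The libraries were oligo(dT)-selected, and which transcripts the reads over these short genes come from was not tested. The same limit holds for every small RNA gene named below. Axin2 (-0.08 ± 0.1, adjusted p = 0.67), Lef1 (-0.66 ± 0.21, adjusted p = 0.15, with the block 0.007) and Dkk2 (0.65 ± 0.21, adjusted p = 0.15, with the block 0.0019) did not pass without the block. Neither did Wnt5a (-0.26 ± 0.06, adjusted p = 0.087, with the block 0.032), Dkk1 (0.25), Shh (-0.76), Fgf10 (-0.05) or Tbx22 (0.19).

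In total 63 genes passed with treatment, 36 higher and 27 lower in mutants, and 2644 had an unadjusted p under 0.05. Median-ratio scaling gave 56 higher and 23 lower. With the litter block 1420 passed (579 higher, 841 lower), and the 8-library batch alone gave 285. With a term for heterozygous embryos 22 passed, and the 6 samples alone gave 2. All 22 named genes had the same sign in both batches, and 21 passed in the 8 libraries. As in untreated embryos, this is no independent test. The count of 63 was 10 to 36 without any of 11 libraries, and 79 without untreated mutant 1. With the block it was 107 to 816 without any library other than untreated mutant 1, untreated control 1 and WAY control 3, and 3528 without WAY control 3. Of the lists, 2 passed. Cell cycle genes were lower (median -0.16, adjusted p = 0.001, and adjusted p = 0.88 with an estimated correlation), with 2 members rising and 13 falling when adjusted over the list alone and none over all genes. Dental markers were lower (median -0.76, adjusted p = 0.016, and adjusted p = 0.24 with an estimated correlation), with Msx1 and Sostdc1 falling over all genes and 3 when adjusted over the list alone. In fry the dental list passed (adjusted p = 0.002), and with the batch term also cell cycle (0.0015), palatal patterning (0.029), nasal (0.029) and periderm (0.038). With the block 7 lists passed in camera, and 0 with an estimated correlation as well (smallest adjusted p = 0.63).

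The average over both treatments, with 6 mutants against 6 controls, asks which mutant effects the arms share. Among palatal patterning genes, 1 of 51 rose (Osr2, 0.93 ± 0.1, SE, adjusted p = 0.0025) and 6 fell. These were Pax9 (-2.06 ± 0.16, adjusted p = 0.00031), Msx1 (-1.33 ± 0.13, 0.0012), Bmp4 (-1.04 ± 0.07, 0.00017), and the forkhead genes Foxf1 (-0.41, 0.033) and Foxe1 (-0.3, 0.039) and the homeobox gene Pitx1 (-0.32, 0.043). Adjusted over the list alone, 4 rose and 11 fell. In the BMP pathway Id2 (0.24) rose and Bmp4, Msx1, Id4 (-0.52) and the BMP antagonist Grem1 (-0.74) fell out of 30 genes, with 4 rising and 6 falling when adjusted over the list alone. Wnt5a (-0.29 ± 0.04, adjusted p = 0.014) and Wnt16 (-0.66 ± 0.12, adjusted p = 0.034) fell among 37 Wnt ligands and receptors, with 1 rising and 2 falling over the list alone. Sostdc1 (-0.91 ± 0.07, adjusted p = 0.00031) and Sfrp2 (-0.36 ± 0.05, adjusted p = 0.012) fell among 15 secreted Wnt antagonists, with 1 rising and 2 falling over the list alone. Without the block no canonical Wnt target passed among 25, while over the list alone 3 rose and 3 fell. The member counts in this paragraph all come from the fit without block, and Lef1 of this list passed with it. Axin2 had -0.06 ± 0.07 (adjusted p = 0.73), Lef1 -0.63 ± 0.15 (adjusted p = 0.088, with the block 0.001) and Dkk2 0.58 ± 0.15 (adjusted p = 0.11, with the block 0.00028). Grem1, Cldn6, Pitx1 and Foxe1 missed the threshold after median-ratio scaling.

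Other genes with the largest changes over both treatments were Ascl5 (-1.64), Hs3st6 (-1.56), Tfap2b (-1.53), Adcy8 (-1.21), Zfp385c (-1.03), Pla2g7 (-0.99) and Slc5a7 (-0.97), which fell, and Gdf7 (1.18), Cbln4 (1.12), Tenm1 (0.89), Aard (0.84), Brinp3 (0.81), Trpc5 (0.81), Pcdh10 (0.64), Ptchd1 (0.63) and Tbx18 (0.63), which rose. Ascl5 and Zfp385c fell less in the 4-library batch (-0.63 and -0.3) than in the 8-library batch (-2.15 and -1.4). Shh, a ligand made by the oral epithelium, differed between batches in sign. It was lower in mutants of the 8-library batch (-1.27 ± 0.07, SE, adjusted p = 0.00033) and had 0.22 in the 4-library batch, with a pooled value of -0.78 ± 0.23 (adjusted p = 0.15). Fgf10 (-0.17), Tbx22 (0.08) and Dkk1 (0.18) did not pass.

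In total 120 genes passed over both treatments, 45 higher and 75 lower, and 2206 had an unadjusted p under 0.05. Median-ratio scaling gave 59 higher and 56 lower. With the litter block 1163 passed (410 higher, 753 lower), and the 8-library batch alone gave 442. All 36 named genes had the same sign in both batches, and 32 passed in the 8 libraries. Since those libraries also made the calls, this is no independent test. The count of 120 was 42 to 71 without any library other than untreated mutant 1 (97), WAY mutant 1 (97) and WAY control 1 (127). With the block it was 517 to 761 without any library other than WAY control 2 (1341) and WAY control 3 (2591). With a term for heterozygous embryos 24 genes passed, 23 of them among the 120.

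Over both treatments 5 lists passed, and 9 with the block, of which 0 passed with an estimated correlation as well (smallest adjusted p = 0.31). In fry the dental (adjusted p = 0.00017) and cell cycle lists (0.037) passed, and oral epithelium (0.66), muscle (0.68) and hypoxia (0.68) did not. With the batch term fry also called oral epithelium, periderm, palatal patterning and ectodysplasin (0.0079 each), nasal (0.014) and secreted Wnt antagonists (0.036). Dental markers were lower (median -0.6, adjusted p = 0.00015) and passed with an estimated correlation (adjusted p = 0.05), but with the block they lost that call (adjusted p = 0.31 with an estimated correlation). The litter differences were -0.84 to -0.33, below 0 in 4 of 4 litters. Msx1 and Sostdc1 fell over all genes and 6 of 13 when adjusted over the list alone. With the block Krt17 (-0.76), Sp6 (-1.84), Fgf3 (-1.63) and Dlx2 (-0.46) were among those that passed as well. Cell cycle genes were lower (median -0.13, adjusted p = 1.1e-07, and adjusted p = 0.85 with an estimated correlation), with the mitotic genes Aurkb (-0.23) and Ccnb2 (-0.24) falling over all genes and 15 falling and 1 rising over the list alone. Oral epithelium markers were lower (median -0.27, adjusted p = 0.012, and adjusted p = 0.86 with an estimated correlation). The tight junction genes Cldn6 (-0.34) fell and Cldn1 (0.26) rose over all genes, the same count as over the list alone. With the block 12 fell, among them Krt17, Dsc3 (-0.78), Epcam (-0.42) and Cdh1 (-0.26). Skeletal muscle markers (median 0.42, adjusted p = 4.1e-05) and hypoxia and glycolysis genes (median 0.1, adjusted p = 0.0091) were higher, each with adjusted p = 0.86 with an estimated correlation and no member passing. With the block P4ha1, P4ha2, Egln3 and Pdk1 of the hypoxia list passed.

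The remaining lists did not pass over both treatments without the block. Their adjusted p was 0.063 for osteogenesis, 0.11 for cartilage, 0.12 for nasal and sensory epithelium (where Gja1 fell, -0.29), 0.16 for the TGF-beta pathway, 0.24 for extracellular matrix and hyaluronan, 0.25 for pericyte and smooth muscle (where Rgs5 rose, 0.52), 0.26 for periderm and 0.28 for secreted Wnt antagonists. It was 0.44 for each of the BMP pathway, ectodysplasin pathway and embryo sex genes, 0.53 for Schwann and melanocyte markers and 0.6 for palatal patterning. It was 0.66 for each of canonical Wnt targets, macrophage markers and dissection stress genes, 0.87 for erythroid markers, 0.9 for each of the hedgehog pathway, FGF pathway and Wnt ligands and receptors, 0.98 for endothelium and 1.0 for neuron markers. With the block the periderm list passed (lower, adjusted p = 0.00026), as did osteogenesis (higher, 0.0086), extracellular matrix (higher, 0.017) and cartilage (higher, 0.017). With an estimated correlation as well, their adjusted p was 0.47 for periderm and 0.62 for each of the other 3. Osteogenesis and cartilage were lower in mutants in 2 of 4 litters (-0.28 and -0.04, -0.34 and -0.25). The median, mean and test differed in sign for canonical Wnt targets (median -0.04, mean -0.1, test upward), the BMP pathway (0.02, -0.03, upward) and the hedgehog pathway (0.01, -0.07, upward). The test was also upward for the FGF pathway (0.0, -0.1), Wnt ligands and receptors (-0.01, -0.01), Schwann and melanocyte markers (-0.02, 0.01) and macrophage markers (-0.01, 0.0), and downward for palatal patterning (0.0, -0.12).

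The treatment comparisons ask what the Wnt agonist changed. No gene passed in limma in mutants (133 with an unadjusted p under 0.05), in controls (2225) or over both genotypes (1415), and voom on recovered reads also gave 0 in each. In treated against untreated mutants Axin2 had a log2 fold change of -0.04 ± 0.1 (SE, n = 3 per group), Lef1 -0.04 ± 0.21, Dkk1 0.32 ± 0.88, Dkk2 0.03 ± 0.21, Sostdc1 -0.02 ± 0.1, Msx1 -0.17 ± 0.18, Bmp4 -0.14 ± 0.1, Osr2 -0.11 ± 0.15 and Pax9 0.05 ± 0.22, each with adjusted p = 1. Wnt5a (-0.06), Shh (-0.14), Fgf10 (-0.01) and Tbx22 (-0.16) did not pass either. Among the smallest p values were those of Snora23 (1.29 ± 0.24, unadjusted p = 0.00031), Snora34 (0.62), Mir677 (0.61) and Mettl18 (0.23) above 0, and of Vstm2a (-0.41), Insig1 (-0.19), Nfkbie (-0.27) and Tmem243 (-0.32) below 0, all with adjusted p = 1.

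In controls Axin2 had 0.02 ± 0.1 (SE, n = 3 per group, adjusted p = 0.94), Lef1 0.02 ± 0.21 (0.97), Dkk1 0.18 ± 0.88 (0.94) and Bmp4 0.3 ± 0.1 (0.21). The other fixed genes ran from -0.38 (Tbx22, adjusted p = 0.29) to 0.22 (Msx1, adjusted p = 0.6). Mir5117 (-2.07), Ppp1cb (-0.62), Ptbp3 (-0.59), Abhd17b (-0.47) and Mdfic (-0.42) were nearest to the threshold (adjusted p = 0.086). Above 0 they were Asf1b (0.23), Tmem199 (0.26), Ccnd3 (0.34), Tubg1 (0.36) and Ndufv3 (0.4). With the batch as a term 375 genes passed in controls (118 higher, 257 lower), 89 with the GC and length correction as well and 0 with a Y-linked score as well, while mutants and the average over genotypes gave 0. The batch term treats littermates as independent. With litter as a random effect or with means per litter and genotype no gene passed in controls in limma (836 and 1248 with an unadjusted p under 0.05). Those fits hold no batch term, and the main fit, also without it, called no gene either. They thus cannot show how far the 375 calls rest on littermates. Without WAY control 3 the batch-term count was 1887, and it was 0 without untreated control 2 or 3 or without WAY mutant 1 or WAY control 1. Without untreated mutants 1, 2 or 3 it was 144, 17 or 108, without untreated control 1 it was 75, without WAY control 2 it was 117 and without WAY mutant 3 it was 152. Over both genotypes the genes with the smallest p values included Mdfic (-0.27), Ptbp3 (-0.34), Far1 (-0.31), Dsel (-0.3), Lemd3 (-0.21), Mir677 (0.58), Snora34 (0.51), Tmem199 (0.2) and Mettl18 (0.23), with adjusted p = 0.3.

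Canonical Wnt target genes did not shift as a list with treatment (adjusted p = 0.79 in mutants, with a median of 0.01, a mean of 0.02 and a downward test, and 0.62 in controls, with 0.02, -0.02 and a downward test). With the batch term the Wnt ligands and receptors list was lower in treated controls (adjusted p = 0.043, and adjusted p = 0.88 with an estimated correlation). Without it, lists that passed were of other kinds. In mutants, hypoxia and glycolysis genes were higher in 21 of 21 members (median 0.28, adjusted p = 6e-09, and adjusted p = 0.93 with an estimated correlation), neuron markers higher in 14 of 18 (median 0.5, adjusted p = 0.00033, and adjusted p = 0.93 with an estimated correlation) and muscle markers higher in 28 of 28 (median 0.24, adjusted p = 0.034, and adjusted p = 1.0 with an estimated correlation). Erythroid markers (median -0.23, adjusted p = 0.0082, and adjusted p = 0.92 with an estimated correlation) and endothelium markers (median -0.04, adjusted p = 0.047, and adjusted p = 0.93 with an estimated correlation) were lower. In controls, neuron markers (median 0.77, adjusted p = 0.0028) and muscle markers (median 0.62, adjusted p = 0.041) were higher, each with adjusted p = 0.98 with an estimated correlation. Over both genotypes the neuron (adjusted p = 8.8e-05), hypoxia (0.0002) and muscle lists (0.004) were higher, each with adjusted p = 1.0 with an estimated correlation. No member of these lists passed over all genes. Adjusted over the list alone, 2 neuron markers rose over both genotypes. In fry no list passed for treatment (smallest adjusted p = 1.0 in mutants, 0.94 in controls and 0.89 over both genotypes), and with the batch term hypoxia and glycolysis genes passed over both genotypes (0.048). In controls the muscle and neuron rises rest largely on the 4-library pair, where muscle means went from -0.62 in untreated control 1 to 0.84 in WAY control 1, against -0.43 and -0.39 to -0.16 and -0.44 in the 8-library controls. Neuron means went from -0.73 to 0.78 in that pair, against 0.02 and -0.18 to 0.11 and 0.68. Each arm holds 2 litters and treatment differs only between litters. Sex largely follows treatment too, with 4 of 6 treated and 1 of 6 untreated embryos male by their Ddx3y level.

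Whether treatment altered the mutant effects was tested by the interaction, and no gene passed (704 with an unadjusted p under 0.05, 0 with the litter block or voom). The 5 largest positive values by p were Snora23 (2.4 ± 0.35, SE, adjusted p = 0.45), Mir5117 (2.26 ± 0.37, adjusted p = 0.73), Ppp1cb (0.57), Abhd17b (0.43) and Nfat5 (0.42). On the negative side they were Id3 (-0.39), Mrpl43 (-0.3), Pik3r2 (-0.27), Med9 (-0.25) and Asf1b (-0.23), with adjusted p = 0.95. Snora23 and Mir5117 are small RNA genes, and the limit given above for reads over such genes holds here. For the fixed genes the interaction was -0.44 ± 0.14 for Bmp4 (adjusted p = 0.95), -0.38 ± 0.26 for Msx1 (0.97), -0.19 ± 0.14 for Sostdc1 (0.97) and -0.06 ± 0.13 for Axin2 (1). No list passed (smallest adjusted p = 0.32). Of the 13 genes called in untreated embryos, all 13 had the same sign with treatment and 5 were smaller, with a median size of 0.85 untreated and 1.01 treated. Treated mutants had moved toward the untreated control by a median of -0.06. For the 74 genes called with the block, 72 had the same sign and 38 were smaller (medians 0.57 and 0.57), with a median move of 0.01. The move and the selection share the untreated mutants, so selection alone pushes the move toward the control and 0 is not its neutral value. Across all genes the untreated mutant effect and the treatment effect in mutants correlated with r = -0.119, against -0.497 simulated from noise. The simulation drew independent noise for each library, with no litter, batch or mutant effect. Differences between litters enter the real treatment effect, so this gap does not show whether treatment reversed mutant effects.

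**Figure D4:**
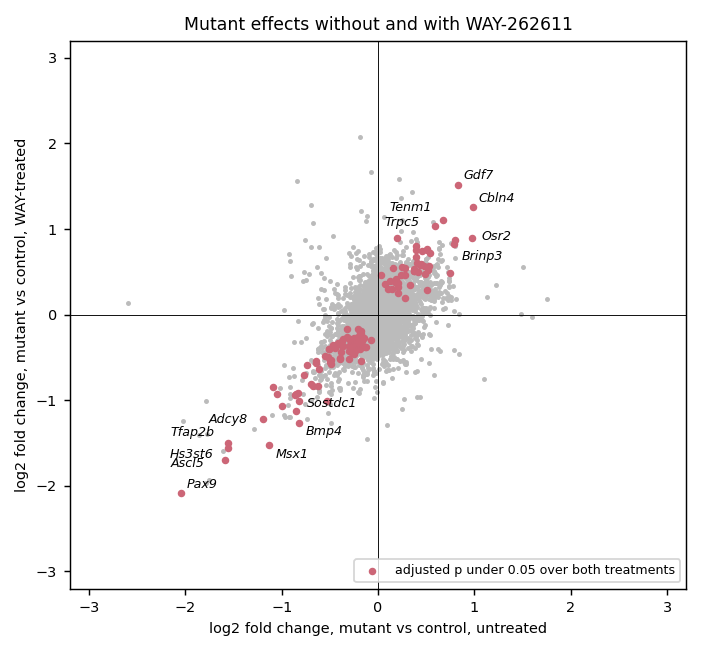
Log2 fold change of mutants against controls for 14107 genes, untreated on the x axis and WAY-treated on the y axis, with genes of adjusted p under 0.05 over both treatments in red. The called genes lie in the lower left and upper right, Pax9 at -2.04 and -2.09 among them, and no gene falls outside the axes.

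Across genes, which are not independent replicates, the mutant effects of the 2 arms correlated with r = 0.457. Of 72 relabellings of genotype, 1 gave an r as large, the real labels themselves, and the highest other was 0.427. Without untreated mutant 1 the r was 0.234, and the share of relabellings with an r as large was over 0.05 there and without WAY control 2 (0.449) or WAY control 3 (0.362). With the block, 26 genes were called higher in both arms against 1.3 by chance and 41 lower against 2.5, and without it 2 and 10 were shared. The chance values treat genes and arms as independent. Both arms come from the same fit with a shared spread per gene, so these values can understate the overlap by chance.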

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

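The batch term, the batch with the Y-linked score, the 8-library batch alone, voom and the GC and length corrections were chosen after the data were seen. The sign of each named gene that passed held under every alternative run: of 308, 562 and 886 values for the 12, 22 and 36 named genes (untreated, treated and over both treatments), 194, 411 and 691 passed again, 114, 151 and 195 missed the threshold and 0 reversed. Every alternative refits the same libraries. For genes picked with no overlap between the sides, leaving out a library cannot turn the sign, so the held signs are no independent support. Of the 70 calls of these named genes, the litter block and the batch term lost 0, median-ratio scaling 4, the heterozygous term 39, and the fit on 6 samples alone 32 of 34. The heterozygous embryos are all in the 8-library batch, so the heterozygous term, fitted without batch, mixes heterozygosity with batch. Each group holds libraries of both batches and the main fit has no batch term, so differences between batches stay in its spread. The litter block and the batch term take them out. How much of the larger counts of those fits comes from this was not tested. Where a cause is not given below, the cause was not tested. Counts of genes with mutant effects stayed within 1.5 times of their values under both pseudocounts, no filter, median-ratio scaling and voom. For untreated embryos the 13 genes became 5 with the heterozygous term, 1 with 6 samples alone and 74 with the litter block. They became 104 with the batch term, 60 with batch and Y-linked score and 50 in the 8-library batch alone. With the block and GC and length correction they became 201. For treated embryos the 63 became 22, 2, 1420, 1807, 1414, 285 and 1038 in the same order. Over both treatments the 120 became 71 with the filter at 5 FPKM (fewer genes tested), 24 with the heterozygous term, 266 with the Y-linked score, 1163 with the block, 1393 with the batch term, 1106 with batch and Y-linked score, 442 in the 8-library batch alone and 1465 with the block and GC and length correction. For treatment in controls, 0 became 375 with the batch term and 89 with the GC and length correction as well. In mutants, over both genotypes and for the interaction no gene passed under any alternative run with all 12 libraries, voom on recovered reads among them (133, 1415 and 704 genes had an unadjusted p under 0.05 in limma).

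With an estimated correlation the lists that passed were 1 instead of 10 in untreated mutants, 0 instead of 2 in treated mutants, 1 instead of 5 over both treatments, and 0 for treatment in mutants, in controls and over both genotypes. In treated mutants 7 lists passed with the block and 7 with the batch term, and over both treatments 9 and 9. With an estimated correlation as well, 0 of these passed (smallest adjusted p = 0.63 and 0.54 in treated mutants, 0.31 and 0.23 over both treatments). For treatment with the batch term 6 passed in controls and 5 over both genotypes, and 0 with an estimated correlation as well (smallest adjusted p = 0.88 and 0.87). The untreated change of Pax9 was -2.04 with 6 samples alone, where it missed the threshold.

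Leaving out each library in turn, the count ran from 0 to 12 in untreated embryos, from 10 to 79 in treated ones, from 42 to 127 over both treatments and from 0 to 1 for treatment in controls. The untreated count was 0 without untreated mutant 2, untreated mutant 3 or untreated control 3, 2 without untreated control 1 or 2, 3 without untreated mutant 1, 4 without WAY mutant 2 and 6 without WAY mutant 3. The treated count was 10 to 36 without each library other than untreated mutant 1, and the count over both treatments was 42 to 71 without each library other than untreated mutant 1, WAY mutant 1 and WAY control 1. The 1 gene in controls appeared without untreated mutant 1 or WAY control 2. The value of Pax9 mutant versus control untreated ran from -2.2 to -1.76, and its call was lost without untreated mutant 2, untreated mutant 3 or untreated control 3. The correlation of the mutant effects of the arms ran from 0.234 (without untreated mutant 1) to 0.518, and it missed the threshold without untreated mutant 1, WAY control 2 or WAY control 3. Depth was 36.8 to 49.8 M reads per library, and which genes it limits was not tested.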

Other observations

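The comparison of batches, the test of a later stage and the test of litters were chosen only after the results were seen. For the GC and length tests and the sex tests, related counts of genes under those corrections had been seen before the tests were fixed. The spread set beside the share of larger effects was also added after that share had been seen.

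The 8-library batch was higher than the 4-library batch in bone genes. Folds here come from the log2(FPKM + 0.5) fit and differ from ratios of the mean FPKM. The bone matrix gene Ibsp had 728 ± 160 FPKM (SD, n = 8) against 16.4 ± 11 (SD, n = 4), 52.2-fold higher. Dmp1 was 17.1-fold higher, the matrix gene Spp1 11.6-fold, Ifitm5 7.68-fold, Col1a1 2.85-fold and the osteoblast factor Sp7 2.58-fold. Of 18 osteogenesis genes 15 were higher and 2 lower (adjusted p = 9.7e-09, and adjusted p = 0.14 with an estimated correlation). Cartilage genes were lower, with Col9a1 5.16-fold, Matn1 5.08-fold, Col2a1 2.38-fold and Sox9 1.57-fold (10 of 14 lower, 2 higher, adjusted p = 0.0037, and adjusted p = 0.39 with an estimated correlation). Skeletal muscle markers were lower too (22 of 28, 1 higher, adjusted p = 1e-05, and adjusted p = 0.47 with an estimated correlation), but 0 of 28 passed among the 7 libraries with Ddx3y under 0.5 FPKM (adjusted p of the list 0.04, and adjusted p = 0.81 with an estimated correlation). Untreated control 1 of the 4-library batch was low in them as well (-0.62 relative to the mean of the 12 libraries).

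Epithelial genes were higher in the 8-library batch. Krt14 had 220 ± 32 FPKM (SD, n = 8) against 92.2 ± 18 (SD, n = 4), Krt5 was 2.58-fold and Krt17 2.71-fold higher, and 22 of 26 oral epithelium markers and 11 of 12 periderm markers were higher with 0 lower (adjusted p = 9.1e-12 and 7.2e-09, each with adjusted p = 0.14 with an estimated correlation). The ciliated cell factor Foxj1 was 15.1-fold and the airway gene Cyp2f2 7.95-fold higher. Among 15 secreted Wnt antagonists 8 were higher, with Dkk1 4.3-fold and Wif1 3.11-fold, and 3 lower (adjusted p = 0.0092, and adjusted p = 0.19 with an estimated correlation), and the Wnt effector Tcf7 was 2.48-fold higher. Hypoxia and glycolysis genes (18 of 21, with Ndrg1 2.69-fold and Slc2a1 1.64-fold, adjusted p = 1.5e-09) and macrophage markers (12 of 15, with Mrc1 1.98-fold and F13a1 2.69-fold, adjusted p = 4.7e-08) were higher, each with adjusted p = 0.14 with an estimated correlation. The embryonic globins Hbb-y (214 ± 29 against 795 ± 80 FPKM, SD) and Hba-x were 3.73-fold and 3.91-fold lower, and the adult globin Hbb-bs was 1.78-fold higher.

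In total 6179 genes differed between the batches (2930 higher and 3249 lower in the 8 libraries). Embryo sex as the whole cause is argued against, since 4156 genes passed among the 7 libraries with Ddx3y under 0.5 FPKM, 3613 of them shared with the full comparison. A GC and transcript length trend is argued against as well, since 7026 genes passed after its correction, with 5610 shared. The embryonic share of beta-globin reached the lowest value of the 4 libraries in 0 of the 8, so a later developmental stage of the 8 libraries may contribute although all carry the same day in their labels. Library preparation and the extent of dissected tissue stay open and were not tested, and each group has members in both batches.

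Of the 1163 genes called over both treatments with the litter block, 79.4% had the larger mutant effect in treated embryos (median size 0.32 against 0.19 untreated). No gene passed for the interaction itself (limma, 704 with an unadjusted p under 0.05, voom 0). Embryo sex stays open: the share was 75.4% with a Y-linked score, but within litters that score varies through untreated mutant 3 alone, and the treated litter of the 8-library batch is all male. With GC and length correction it was 70.2%, above the bound of 65% by less than the SD of 7.6 over the fits that leave out a library, so that trend cannot be told apart from the pattern. The untreated litter of the 4-library batch may carry part of it, since the share was 64.6% without untreated control 1 and 64.8% without untreated mutant 1. With the litter block each of these fits drops that litter's only pair, so neither points to a single library. The WAY controls stand apart on the second principal component (-16, -25.9 and -10.2, the other 9 libraries -0.1 to 16.7), and WAY controls 2 and 3 differ more (chi-square per degree of freedom 34.74) than the other pairs within a group and batch (4.35 to 9.47). WAY control 2 is heterozygous and WAY control 3 wild-type, while each of those other pairs shares its genotype. Without WAY control 1, 2 or 3 the share was 84.6%, 75.2% or 88.7%. Leaving out WAY control 1 likewise drops the only pair of the treated litter in the 4-library batch. Treatment stays an open explanation too, as it differs only between litters.

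Hypoxia and glycolysis genes were higher in treated than in untreated mutants, in 21 of 21 genes with the batch term (mean 0.27, adjusted p = 8.5e-23, and adjusted p = 0.16 with an estimated correlation). A GC and length trend is argued against, since the mean was 0.27 after its correction. With the Y-linked score the mean was 0.23, but within litters that score varies through untreated mutant 3 alone. The treated litter of the 8-library batch is all male, so embryo sex stays open. In controls the list missed the threshold with that score (adjusted p = 0.067). Relative to the mean of the 12 libraries, the list averaged -0.4 in the untreated and -0.3 in the treated litter of the 4-library batch, and 0.02 and 0.33 in those of the 8-library batch. The treated litter was thus higher in each batch. Litters of the same arm lie in different batches, so the 0.63 between them (against 0.21 between arms) mixes batch with litter and gives no measure of litter spread. Each batch holds 1 litter per arm, so litter and treatment cannot be told apart.

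Other splits of the samples were refitted for each count of genes. Splits of 6 samples are too few (10) for a share under 0.05: the real split gave 13 genes in untreated embryos (highest other 0), 63 in treated embryos (highest other 2), and 0 for treatment in mutants and in controls (limma, 133 and 2225 genes with an unadjusted p under 0.05, voom 0, highest other 0 in each), with 1, 1, 10 and 10 splits giving as many. Over both treatments 2 of 100 splits gave as many as the real 120. These splits ignore batch and litter, which the real split balances, so their share cannot exclude chance for that count. The other, with 134 genes, put all 4 libraries of the 4-library batch on the same side. With the litter block, 1 of 72 splits that keep the genotype numbers of each litter gave as many as the real 1163 (highest other 3). Chance can be excluded there at 0.05. For treatment over both genotypes and for the interaction the real count was 0 in limma (1415 and 704 genes with an unadjusted p under 0.05, voom 0), so 100 of 100 splits gave as many by construction and say nothing about chance. For treatment the highest other, 1919, follows the batches and points to that structure, and for the interaction it was 3.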
